A study of Rattus norvegicus with 12 samples.

How the data were processed

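RNA sequencing was done on rat Schwann cells in 12 libraries of 4 groups, with 3 libraries per group: cells alone, cells with monocyte-derived macrophages (MDM), and cells with macrophages induced by culture supernatant of BxPC-3 (BxTAM) or MIA PaCa-2 (MiaTAM) pancreatic cancer cells. Groups were read from the sample labels. The labels title the cells alone Rsc96, while their short descriptions and the table's headers write HSC96, and the MDM libraries are headed PBMC in the table. The species of the macrophages is not given in the sources used here, and the labels name rat as the organism of every sample. A further kind of TAM named in the design text is not analysed here.

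Per the labels' protocols, total RNA was extracted with a column kit, its integrity was checked, and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, CASAVA, HISAT2, StringTie 1.3.0 and the genome build Rnor_6.0 were used. The tool that made the counts, the annotation release, the strand setting and any gene filter are not given in the sources used here. The deposited table holds raw counts per gene for each library, per the file headers, as whole numbers without normalization. It also holds FPKM values, which the authors scaled by gene length and by the total count of the same library. The gene length implied by count and FPKM varied by at most 0.0945% within a gene, so both columns describe the same counts. The table has 30957 genes, each with an Ensembl identifier, of which 17963 had a count in at least 1 library.

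Library totals were 17491359, 19351476 and 18682148 counts for cells alone, 17408450, 17975207 and 21506669 for MDM, 18677039, 17400979 and 18150439 for BxTAM, and 19043650, 16555215 and 18615916 for MiaTAM co-culture. Replicates were compared for duplicated libraries, and none was found.

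The main analysis was run in edgeR 4.0.16 under R 4.3.3 on the counts. Genes were kept by filterByExpr by group, which left 12360, and libraries were scaled by TMM, with factors from 0.98 to 1.01. The median gene shifted by at most 0.00894 on the log2 scale in any comparison. All 12 libraries entered 1 quasi-likelihood fit with 1 mean per group and no block, with a common dispersion of 0.00218, 8 residual degrees of freedom and 11.97 prior degrees of freedom. The 6 comparisons were MDM co-culture, BxTAM and MiaTAM each against cells alone, BxTAM and MiaTAM each against MDM co-culture, and MiaTAM against BxTAM. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and the number of called genes at 2-fold or more is given beside them. The standard error of a log2 change was taken as its size over the square root of the F statistic. Where a group had 0 counts, the fold was computed against a floor of 3 counts over the group, and with 1 to 3 counts a 95% counting interval of the ratio was given.

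Of 29 gene lists written before the data were examined, 28 had at least 5 tested members. They cover Schwann identity, repair and myelin genes, neurotrophic and guidance genes, the FGF and PI3K axis, inflammatory NF-kappaB genes, interferon, antigen presentation, TGF-beta targets, extracellular matrix, proteases and migration, S phase, mitosis, MYC and ribosome biogenesis, ribosomal proteins, MAPK output, immediate early genes, p53, NRF2, the unfolded protein and integrated stress responses, glycolysis and hypoxia, oxidative phosphorylation, cholesterol, LXR and lipid genes, and markers of macrophages, lymphocytes, epithelium, fibroblasts and the mitochondrial chromosome. The immediate early and mitochondrial chromosome lists were written as checks of handling and RNA quality. Of 753 symbols, 711 were found by symbol, 10 through RefSeq names, 2 by description and 14 not at all, and 16 stood on several genes. Lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation and with fry.

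The genes named in the text follow a rule written before the data were examined. It takes the 10 largest rises and 10 largest falls per comparison among called genes with a usable symbol, a mean of at least 1 CPM in the higher group and no overlap between the libraries of both groups. It adds up to 4 members per list with the smallest p, and always names a fixed set with Il33, Gfap, Myc, Fgf2, Fgfr1, Sox10, S100b and Ngfr. Of these, Il33, Gfap, Myc, Fgf2 and Fgfr1 were chosen because the study of this series is known for them. Their choice was therefore not independent of these data. Some genes that the rule names are not reported here. Values of the TAM overlap were set beside 20 simulations of unchanged groups with the same controls.

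The analysis was tested on data simulated for BxTAM against MDM co-culture. Of 12160 genes simulated as unchanged, before the filter, 10 were called, and camera gave 4 of 100 random lists a p under 0.05. Settings varied were size factors of DESeq2 in edgeR, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, a mean of at least 5 CPM, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) over 11546 genes, the replicate number as a block, a fit of only the groups compared, and leaving out each library in turn. Tests, filters, lists and these settings were chosen before the data were examined. Chosen after seeing the data were scaling by library total only, upper-quartile factors, the TGF-beta list without Pmepa1 and the TAM overlap without the cell cycle lists. Figures were drawn with matplotlib 3.10.9.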

Results

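Messenger RNA was profiled by sequencing in rat Schwann cells in 4 groups of 3 libraries. The cells were grown alone, with monocyte-derived macrophages (MDM), with macrophages induced by medium of the human pancreatic cancer line BxPC-3 (BxTAM), or with macrophages induced by medium of a second human pancreatic cancer line, MIA PaCa-2 (MiaTAM). The sample titles name a line only for the cells alone, Rsc96. It was taken as RSC96, an immortalised line derived from rat nerve. Total gene counts ran from 16555215 to 21506669 per library. Of 30957 annotated genes, 17963 had a count in at least 1 library and 12360 entered the tests. The labels do not say that the 3 libraries of a group came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. Levels are CPM values of TMM-scaled counts, as mean ± SD over 3 libraries, and changes are log2 fold changes ± standard error from 3 libraries against 3. Counting intervals and floors cover counting error alone. The strand setting of the counting is not given in the sources used here, so genes that overlap on opposite strands are uncertain, as are families that share reads, such as ribosomal proteins with their pseudogenes, Gapdh, RT1, the metallothioneins and the Cxcl and Clca families.

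The libraries separated by group. The first principal component, with 56.5% of the variance, placed the 3 libraries of Schwann cells alone apart from the 9 co-culture libraries, and the second, with 15.2%, placed the MDM co-cultures apart from both TAM co-cultures. Genes of the Schwann lineage were unevenly present. Sox10, the central transcription factor of the lineage, had 1 count in all 12 libraries together. S100b, a Schwann cell marker, had 8 to 14 counts per group. Neither entered the tests. Vim, an intermediate filament gene, stood at 1870 ± 85.4 CPM in MDM co-culture, and Erbb3, the neuregulin co-receptor, at 7.14 ± 0.871 CPM in cells alone.

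**Figure D1:**
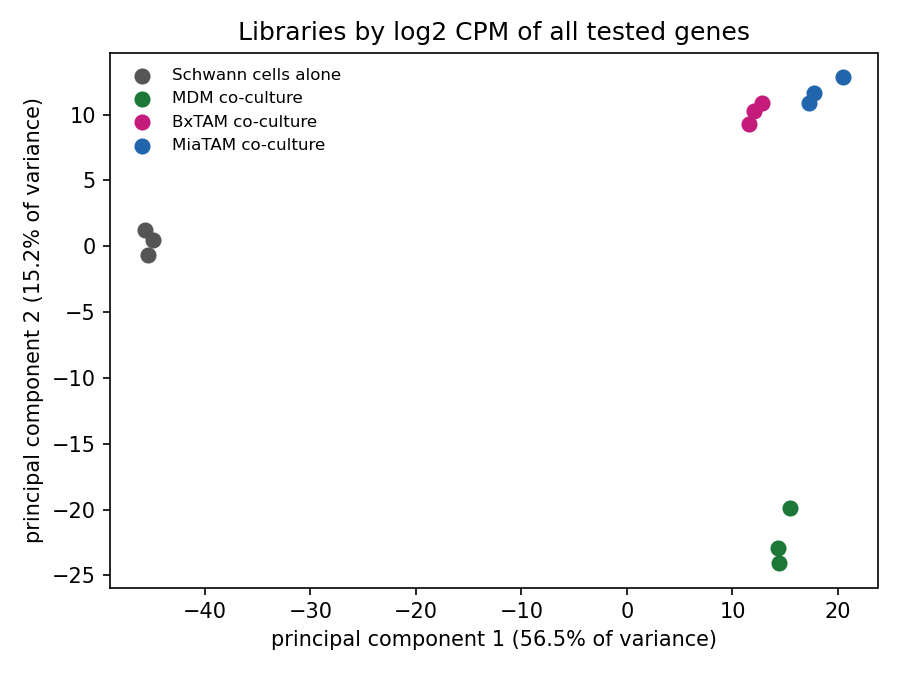
Each point is 1 of 12 libraries, placed by its first and second principal components of log2 CPM over 12360 tested genes, with 56.5% and 15.2% of the variance. The Schwann cells alone lie at one end of the first component, and the MDM co-cultures lie apart from both TAM co-cultures on the second.

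The first comparison asked what macrophages without tumour induction change in Schwann cells. Genes of DNA replication fell the most as a group in MDM co-culture. Mcm3, a subunit of the replicative helicase, went from 147 ± 1.57 CPM alone to 28.9 ± 0.945 CPM (-2.34 ± 0.05), Mcm4 fell 5.01-fold, and Cdc6, which loads the helicase at origins, changed by -2.74 ± 0.08. The collagen gene Col1a1 rose 4.36-fold and the endoplasmic reticulum chaperone gene Hspa5 rose 3.94-fold, from 1105 ± 29.0 to 4355 ± 264 CPM. Il33, which encodes a nuclear alarmin cytokine, fell from 219.6 ± 7.60 to 111 ± 1.99 CPM (-0.99 ± 0.05).

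Proliferation genes fell throughout in MDM co-culture. In the S-phase list, 0 of 31 tested members rose and 30 fell (0 and 30 adjusted over the list alone), with a median change of -1.37 (camera, adjusted p = 6.8e-53). Orc1, of the origin recognition complex, changed by -2.48 ± 0.09. In the list of G2 and mitosis genes, 0 of 29 tested members rose and 29 fell (0 and 29 adjusted over the list alone), with a smaller median of -0.79 (camera, adjusted p = 2.1e-24). Top2a, the topoisomerase of dividing cells, changed by -0.93 ± 0.04, Mki67, the Ki-67 proliferation antigen, by -1.07 ± 0.05 and Kif20a, a mitotic kinesin, by -0.79 ± 0.04. In the list of MYC targets and ribosome biogenesis, 0 of 30 tested members rose and 30 fell (0 and 30 adjusted over the list alone), with a median of -0.91 (camera, adjusted p = 1.9e-20). Odc1, the first enzyme of polyamine synthesis, changed by -1.03 ± 0.04, Nop56, a nucleolar protein, by -1.26 ± 0.05 and Myc itself by -0.63 ± 0.06. All 3 lists held with an estimated correlation.

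Matrix and protease genes rose. In the extracellular matrix list, 18 of 27 tested members rose and 4 fell (18 and 4 adjusted over the list alone), with a median of 0.52 (camera, adjusted p = 6.0e-10). Col1a1 reached 73.7 ± 1.02 CPM, Spp1, which encodes osteopontin, changed by 1.40 ± 0.05 and Col6a2 by 1.24 ± 0.06. In the protease and migration list, 18 of 27 tested members rose and 3 fell (18 and 3 adjusted over the list alone) (camera, adjusted p = 5.9e-06). Mmp13, a collagenase, rose 3.60-fold and Adamts4, an aggrecan-cleaving protease, 2.82-fold. Both lists held with an estimated correlation. The TGF-beta target list also passed, and 16 of 25 tested members rose and 4 fell (16 and 4 adjusted over the list alone) (camera, adjusted p = 0.00768; adjusted p = 0.108 with an estimated correlation).

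The largest rises were of genes close to silent in cells alone. Pmepa1, a TGF-beta-induced membrane protein that dampens SMAD signalling, had 0 counts alone and 249 in MDM co-culture, at least 82.4-fold higher by the observed count against a floor of 3 counts over the group, or 66.5-fold by the lower 95% counting limit. Sulf2, a heparan sulfate endosulfatase, had 0 and 136 counts, at least 45.02-fold higher by that floor, or 36.1-fold by the lower limit. Tspan18, a tetraspanin, had 1 and 111 counts, a ratio whose 95% counting interval ran from 19.4 to 4393. Pmepa1 lies on chromosome 3, 171294856 to 171342646, Sulf2 on chromosome 3, 162791355 to 162872831 and Tspan18 on chromosome 3, 82097068 to 82236664 of Rnor_6.0. Dhrs3, a retinaldehyde reductase, rose 9.85-fold to 15.9 ± 0.881 CPM. The largest fall was that of Slc7a11, the cystine transporter subunit, from 26.6 ± 0.925 to 2.14 ± 0.342 CPM (-3.63 ± 0.11).

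Stress, metabolic and immune genes divided within their lists. In the unfolded protein and integrated stress list, 15 of 29 tested members rose and 12 fell (15 and 12 adjusted over the list alone), its median was 0.27 and its mean -0.09, and it did not pass (camera, adjusted p = 0.796). Hspa5 rose, while Chac1, a glutathione-degrading enzyme induced by ATF4, changed by -1.57 ± 0.05 and the amino acid transporter Slc7a5 by -1.78 ± 0.06. In the glycolysis and hypoxia list, 22 of 36 tested members rose and 6 fell (22 and 6 adjusted over the list alone) (camera, adjusted p = 1.5e-08; adjusted p = 0.0910 with an estimated correlation). The enolase gene Eno2 rose 2.49-fold and the collagen prolyl hydroxylase gene P4ha1 2.48-fold. In the inflammatory NF-kappaB list, 6 of 32 tested members rose and 14 fell (6 and 14 adjusted over the list alone) (camera, adjusted p = 0.0142; adjusted p = 0.0910 with an estimated correlation). The neutrophil chemokine genes Cxcl1 and Cxcl6 changed by -1.51 ± 0.05 and -2.69 ± 0.18, and Il10, an anti-inflammatory cytokine, by -2.49 ± 0.16. The interferon list did not pass (camera, adjusted p = 0.405), although Gbp2 changed by -1.18 ± 0.05 and Oasl by 1.19 ± 0.06, both interferon-induced. Egr1, an immediate early transcription factor, rose 2.42-fold. In the immediate early list 9 of 12 tested members rose and 2 fell (9 and 2 adjusted over the list alone) (camera, adjusted p = 0.00184; adjusted p = 0.0910 with an estimated correlation). That list is a check of dissociation and handling. Here and in the other comparisons, a handling difference between groups cannot be told apart from a response to co-culture. In the MAPK output list 18 of 28 tested members rose and 6 fell (18 and 6 adjusted over the list alone) (camera, adjusted p = 0.00538; adjusted p = 0.156 with an estimated correlation).

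Further lists passed with the preset correlation alone. Cholesterol genes had a median of 0.19 (camera, adjusted p = 0.0377; adjusted p = 0.203 with an estimated correlation). Ribosomal protein genes had a median of 0.18 (camera, adjusted p = 0.00709; adjusted p = 0.360 with an estimated correlation). The p53 list had a median of 0.17 (camera, adjusted p = 0.0296; adjusted p = 0.149 with an estimated correlation), with the kinase gene Plk3 up 2.10-fold and the cell cycle inhibitor gene Cdkn1a up 1.65-fold. Genes of the mitochondrial chromosome had a median of -0.60 (camera, adjusted p = 2.9e-04; adjusted p = 0.334 with an estimated correlation). The fibroblast marker list, which shares Col1a1 with the matrix list, passed with 6 of 6 tested members higher (camera, adjusted p = 0.00446; adjusted p = 0.0914 with an estimated correlation). Of 7 tested macrophage markers, 6 rose (camera, adjusted p = 0.0201; adjusted p = 0.0910 with an estimated correlation), and the list missed the threshold without a filter on low counts (adjusted p = 0.0867). Itgax, the CD11c integrin, went from 17.2 to 46.2 CPM and Lcp1, a leukocyte actin-bundling protein, from 1.56 to 3.62 CPM, while 20 of the 26 markers stayed under 1 CPM in every group.

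Schwann cell lists gave no call in MDM co-culture, though single members changed. In the Schwann identity list, 6 of 9 tested members rose and 0 fell (6 and 0 adjusted over the list alone) (camera, adjusted p = 0.120). Dhh, the Schwann cell hedgehog ligand, rose 2.22-fold and Ngfr, the p75 neurotrophin receptor, changed by 2.34 ± 0.38 at 2.16 ± 0.692 CPM. Gfap, a glial intermediate filament, fell from 2.84 ± 0.171 to 1.22 ± 0.222 CPM (-1.21 ± 0.22). In the repair Schwann list, 10 of 20 tested members rose and 5 fell (10 and 5 adjusted over the list alone) (camera, adjusted p = 0.264). In the myelin list, 4 of 11 tested members rose and 3 fell (4 and 3 adjusted over the list alone) (camera, adjusted p = 0.871). Cadm4, an adhesion protein of the axon-glia contact, rose 2.42-fold and Egr2, the myelination transcription factor, 2.19-fold. Cxcl12, a chemokine of the neurotrophic and guidance list, changed by -1.57 ± 0.04, and the list did not pass (camera, adjusted p = 0.916). In the FGF and PI3K list, which includes Il33 and Myc, 11 of 23 tested members rose and 8 fell (11 and 8 adjusted over the list alone) (camera, adjusted p = 0.916). Its median, mean and test differed in sign. Fgfr1, an FGF receptor, changed by 0.93 ± 0.19 at 2.25 ± 0.147 CPM, and Fgf2, one of its ligands, was not called (0.03 ± 0.16).

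By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8047 of 12360 genes changed between MDM co-culture and cells alone, 3952 higher and 4095 lower. Which direction held more genes depended on the scaling, with 4579 higher and 3497 lower with upper-quartile factors, chosen after seeing the data, and 3311 and 4262 with limma-trend on log2(FPKM + 1). At 2-fold or more, 635 were higher and 411 lower. Il33 had an adjusted p of 2.9e-13 and Mcm3 one of 1.7e-18 by that test. The antigen presentation, LXR and lipid, epithelial marker, NRF2 and oxidative phosphorylation lists did not pass (camera, adjusted p = 0.248, 0.453, 0.796, 0.796 and 0.923). The signs of median, mean and test differed in the epithelial, unfolded protein and oxidative phosphorylation lists. The lymphocyte marker list was not tested, since 1 member, Lck, passed the count filter.

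**Figure D2:**
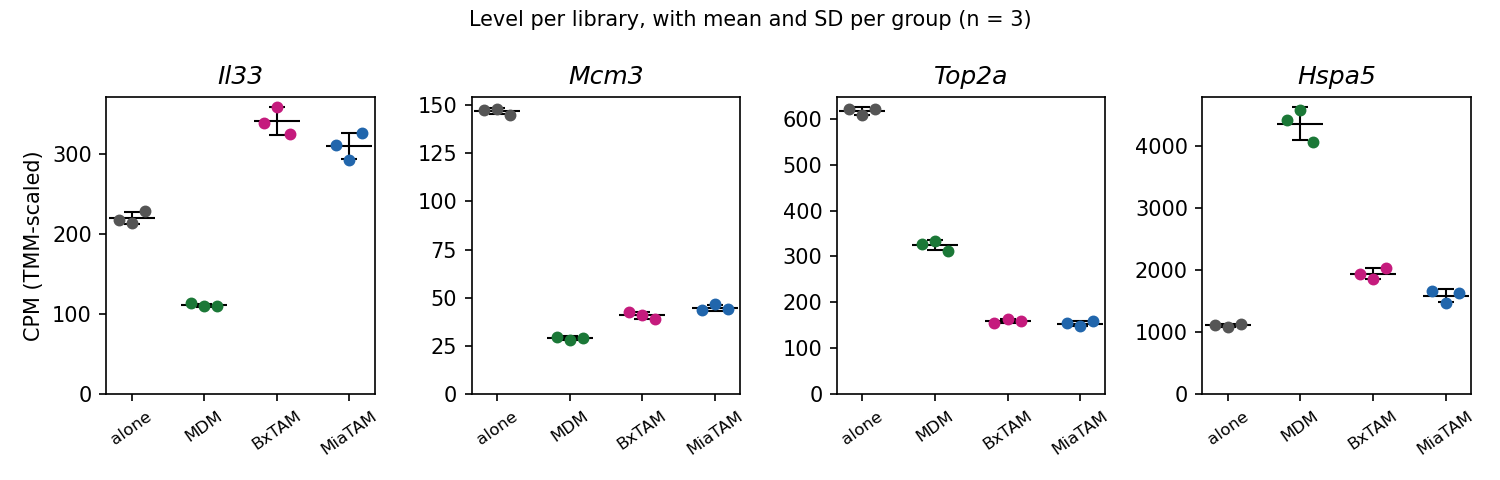
Level of Il33, Mcm3, Top2a and Hspa5 in CPM on a linear axis from 0, with 1 point per library and black bars for the mean and SD of 3 libraries. Il33 stood at 219.6 CPM alone, 111 with MDM, 341 with BxTAM and 309.5 with MiaTAM, and Top2a was lowest in both TAM co-cultures.

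The comparison of BxTAM with MDM co-culture asked what induction of the macrophages by BxPC-3 medium adds. Il33 rose 3.07-fold, from 111 ± 1.99 to 341 ± 17.1 CPM (1.62 ± 0.05). The gene lies on chromosome 1, 248132090 to 248147029 of Rnor_6.0. Csf3, which encodes the granulocyte colony-stimulating factor, rose 2.64-fold, and Cxcl12 2.79-fold, from 79.1 ± 3.63 to 221 ± 4.65 CPM. Mitotic genes fell, among them Kif20a (-1.19 ± 0.04) and the cyclin gene Ccna2 (-1.33 ± 0.06). Hspa5 fell from 4355 ± 264 to 1941 ± 89.4 CPM, and Egr1 from 260.0 ± 5.81 to 90.2 ± 3.09 CPM.

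Inflammatory genes rose as a group in BxTAM co-culture. In the NF-kappaB list, 23 of 32 tested members rose and 2 fell (23 and 4 adjusted over the list alone), with a median of 0.55 (camera, adjusted p = 2.3e-23). Cxcl1 changed by 1.13 ± 0.05 and Csf1, the macrophage colony-stimulating factor, by 0.77 ± 0.04. Cxcl3, a further chemokine of neutrophils, changed by 2.19 ± 0.15 and Il10 by 2.53 ± 0.16, both among the 10 largest rises. In the list of G2 and mitosis genes, 0 of 29 tested members rose and 29 fell (0 and 29 adjusted over the list alone), with a median of -0.84 (camera, adjusted p = 9.9e-95). S-phase genes did not follow. In that list, 11 of 31 tested members rose and 8 fell (12 and 8 adjusted over the list alone) (camera, adjusted p = 0.0645), and it passed without BxTAM library 3 (adjusted p = 0.0227) and without MDM library 3 (adjusted p = 0.0490). The helicase genes Mcm6 and Mcm3 rose by 0.66 ± 0.04 and 0.50 ± 0.05.

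Metabolic genes moved in both directions. In the glycolysis and hypoxia list, 1 of 36 tested members rose and 28 fell (1 and 29 adjusted over the list alone), with a median of -0.30 (camera, adjusted p = 2.2e-17). Ero1l, an oxidase of the endoplasmic reticulum induced by hypoxia, changed by -0.92 ± 0.06, and Gpi, a glycolytic isomerase, by -0.58 ± 0.04. In the cholesterol list, 17 of 26 tested members rose and 0 fell (19 and 1 adjusted over the list alone) (camera, adjusted p = 6.9e-13). Fdps, the farnesyl diphosphate synthase, changed by 0.70 ± 0.05 and Msmo1, a sterol oxidase, by 0.73 ± 0.04. In the unfolded protein and integrated stress list, 9 of 29 tested members rose and 15 fell (9 and 16 adjusted over the list alone) (camera, adjusted p = 0.00133), with Hspa5 at -1.17 ± 0.05 and the chaperone gene Hsp90b1 at -0.83 ± 0.04. These lists, with the NF-kappaB and mitosis lists, were the 5 that held with an estimated correlation. In the LXR and lipid list, 8 of 15 tested members rose and 2 fell (8 and 3 adjusted over the list alone) (camera, adjusted p = 0.00133; adjusted p = 0.0628 with an estimated correlation), and Fasn, the fatty acid synthase, changed by 0.59 ± 0.05. In the MYC and ribosome biogenesis list, 15 of 30 tested members rose and 1 fell (17 and 2 adjusted over the list alone) (camera, adjusted p = 0.00120; adjusted p = 0.0992 with an estimated correlation), and Myc rose by 0.45 ± 0.06.

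Neurotrophic, interferon and other lists passed with the preset correlation alone. In the neurotrophic and guidance list, 8 of 27 tested members rose and 4 fell (10 and 4 adjusted over the list alone) (camera, adjusted p = 0.00145; adjusted p = 0.0628 with an estimated correlation), with Bdnf, the brain-derived neurotrophic factor, at 0.43 ± 0.07 and Lif, a cytokine of nerve injury, at 0.68 ± 0.09. In the interferon list, 15 of 38 tested members rose and 4 fell (16 and 4 adjusted over the list alone) (camera, adjusted p = 0.00556; adjusted p = 0.137 with an estimated correlation), with Parp14 at 0.91 ± 0.05. The immediate early list had a median of -0.16 (camera, adjusted p = 0.00145; adjusted p = 0.0628 with an estimated correlation). The NRF2 list had a median of -0.23 (camera, adjusted p = 0.0179; adjusted p = 0.0628 with an estimated correlation), the ribosomal protein list one of -0.13 (camera, adjusted p = 0.00269; adjusted p = 0.282 with an estimated correlation), and the mitochondrially encoded list one of 0.09 (camera, adjusted p = 0.00556; adjusted p = 0.425 with an estimated correlation). The TGF-beta list had a median of -0.10 (camera, adjusted p = 0.0246; adjusted p = 0.169 with an estimated correlation) and missed the threshold without Pmepa1 (adjusted p = 0.113), with a mean of at least 5 CPM (adjusted p = 0.1003) and with no filter on low counts (adjusted p = 0.0800). Pmepa1 fell from 4.44 ± 0.341 to 0.334 ± 0.152 CPM, and Ctgf, a matricellular target of TGF-beta and YAP, changed by -1.38 ± 0.10. The MAPK list had a median of -0.09 (camera, adjusted p = 0.0387; adjusted p = 0.250 with an estimated correlation) and missed the threshold without BxTAM library 2, BxTAM library 3 or MDM library 2 (adjusted p = 0.0544, 0.0612 and 0.0665), with a mean of at least 5 CPM (adjusted p = 0.0712) and with no filter (adjusted p = 0.0942).

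Several of the largest changes lay outside the lists. Clca4l, of the family of calcium-activated chloride channel regulators, rose 7.82-fold to 29.2 ± 1.05 CPM. Slc17a6, a vesicular glutamate transporter, rose from 0.403 ± 0.151 to 2.38 ± 0.114 CPM. Nptxr, the neuronal pentraxin receptor, fell 3.46-fold, from 588 ± 10.5 to 170.3 ± 7.51 CPM, and Dhrs3 4.65-fold. Ngfr fell from 2.16 ± 0.692 to 0.815 ± 0.196 CPM. Gfap and Fgfr1 did not pass (0.12 ± 0.25 and 0.17 ± 0.17), nor did Fgf2 (0.24 ± 0.15).

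By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4291 of 12360 genes differed between BxTAM and MDM co-culture, 2153 higher and 2138 lower, and 89 were higher and 127 lower by 2-fold or more. With upper-quartile factors, chosen after seeing the data, 2098 were higher and 2170 lower. Il33 had an adjusted p of 8.6e-16 by that test. On counts simulated for this comparison for 12360 genes, of which 12261 passed the filter and were tested, it recovered 26 of 50 genes changed 1.2-fold, 45 of 50 changed 1.5-fold, 47 of 50 changed 2-fold and 50 of 50 changed 4-fold.

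The comparison of MiaTAM with MDM co-culture put the same question for MIA PaCa-2 medium. Il33 rose 2.79-fold, from 111 to 309.5 CPM (1.48 ± 0.05). Clca4l changed by 2.58 ± 0.10, Il10 rose 4.75-fold, and Il6, a proinflammatory cytokine gene, rose from 0.237 ± 0.101 to 1.02 ± 0.179 CPM. Kif11, a mitotic kinesin, and Top2a fell (-1.17 ± 0.04 and -1.08 ± 0.04). Ddit3, the CHOP transcription factor of the stress response, fell from 203 to 74.2 CPM (-1.45 ± 0.07), and Hspa5 changed by -1.46 ± 0.05.

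The NF-kappaB list rose and the mitosis list fell. In the former, 22 of 32 tested members rose and 3 fell (22 and 3 adjusted over the list alone), with a median of 0.52 (camera, adjusted p = 1.4e-19). Csf1 and Cxcl1 changed by 0.84 ± 0.04 and 0.98 ± 0.05, while Cxcl10, an interferon-induced chemokine, fell 1.99-fold. In the mitosis list, 0 of 29 tested members rose and 29 fell (0 and 29 adjusted over the list alone), with a median of -0.92 (camera, adjusted p = 2.6e-84). In the S-phase list, 15 of 31 tested members rose and 6 fell (15 and 6 adjusted over the list alone) (camera, adjusted p = 0.00447; adjusted p = 0.131 with an estimated correlation), with Mcm6 at 0.71 ± 0.04 and the cyclin gene Ccne1 at 0.75 ± 0.09. In the glycolysis and hypoxia list, 2 of 36 tested members rose and 29 fell (2 and 31 adjusted over the list alone) (camera, adjusted p = 9.0e-17), and Car12, a carbonic anhydrase, changed by -0.80 ± 0.05. In the unfolded protein and integrated stress list, 8 of 29 tested members rose and 14 fell (8 and 15 adjusted over the list alone) (camera, adjusted p = 5.5e-06), with Hsp90b1 at -1.05 ± 0.04. In the LXR and lipid list, 7 of 15 tested members rose and 0 fell (7 and 0 adjusted over the list alone) (camera, adjusted p = 1.3e-04), with Angptl4, an inhibitor of lipoprotein lipase, at 0.70 ± 0.04. The S-phase list aside, these lists held with an estimated correlation.

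Other groups were split. In the neurotrophic and guidance list, 11 of 27 tested members rose and 2 fell (11 and 3 adjusted over the list alone) (camera, adjusted p = 0.00447; adjusted p = 0.108 with an estimated correlation), with Lif at 0.92 ± 0.08 and Cxcl12 at 0.80 ± 0.04. In the MYC and ribosome biogenesis list, 17 of 30 tested members rose and 5 fell (17 and 5 adjusted over the list alone) (camera, adjusted p = 2.6e-04; adjusted p = 0.108 with an estimated correlation), and Myc rose by 0.51 ± 0.06. The mitochondrially encoded list had a median of 0.22 (camera, adjusted p = 2.5e-05; adjusted p = 0.330 with an estimated correlation). The matrix and TGF-beta lists did not pass (camera, adjusted p = 0.913 and 0.641), though Spp1 changed by -1.13 ± 0.05 and Ctgf by -1.33 ± 0.10. Mmp13 changed by -1.31 ± 0.07, and its protease list did not pass (camera, adjusted p = 0.0604). That list passed without MiaTAM library 2 (adjusted p = 0.0440) or library 3 (adjusted p = 0.0381), with no filter on low counts (adjusted p = 0.0163) and with the replicate number as a block (adjusted p = 0.0471). Fgfr1 rose from 2.25 ± 0.147 to 4.10 ± 0.160 CPM. Ngfr was not called (-0.62 ± 0.30), but passed without MiaTAM library 1 (log2 change -1.06, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0156). Gfap and Fgf2 were not called (0.04 ± 0.25 and 0.21 ± 0.15).

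By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5062 of 12360 genes differed between MiaTAM and MDM co-culture, 2453 higher and 2609 lower, with 108 higher and 89 lower by 2-fold or more. The larger direction turned with the scaling, to 2659 higher and 2396 lower with upper-quartile factors and 2620 and 2403 with library totals only, both chosen after seeing the data, and 2453 and 2315 with limma-trend on log2(FPKM + 1). Il33 had an adjusted p of 6.6e-15 by that test. The median, mean and test differed in sign in the p53, immediate early, antigen presentation, fibroblast, epithelial, myelin, matrix and interferon lists, none of which passed.

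**Figure D3:**
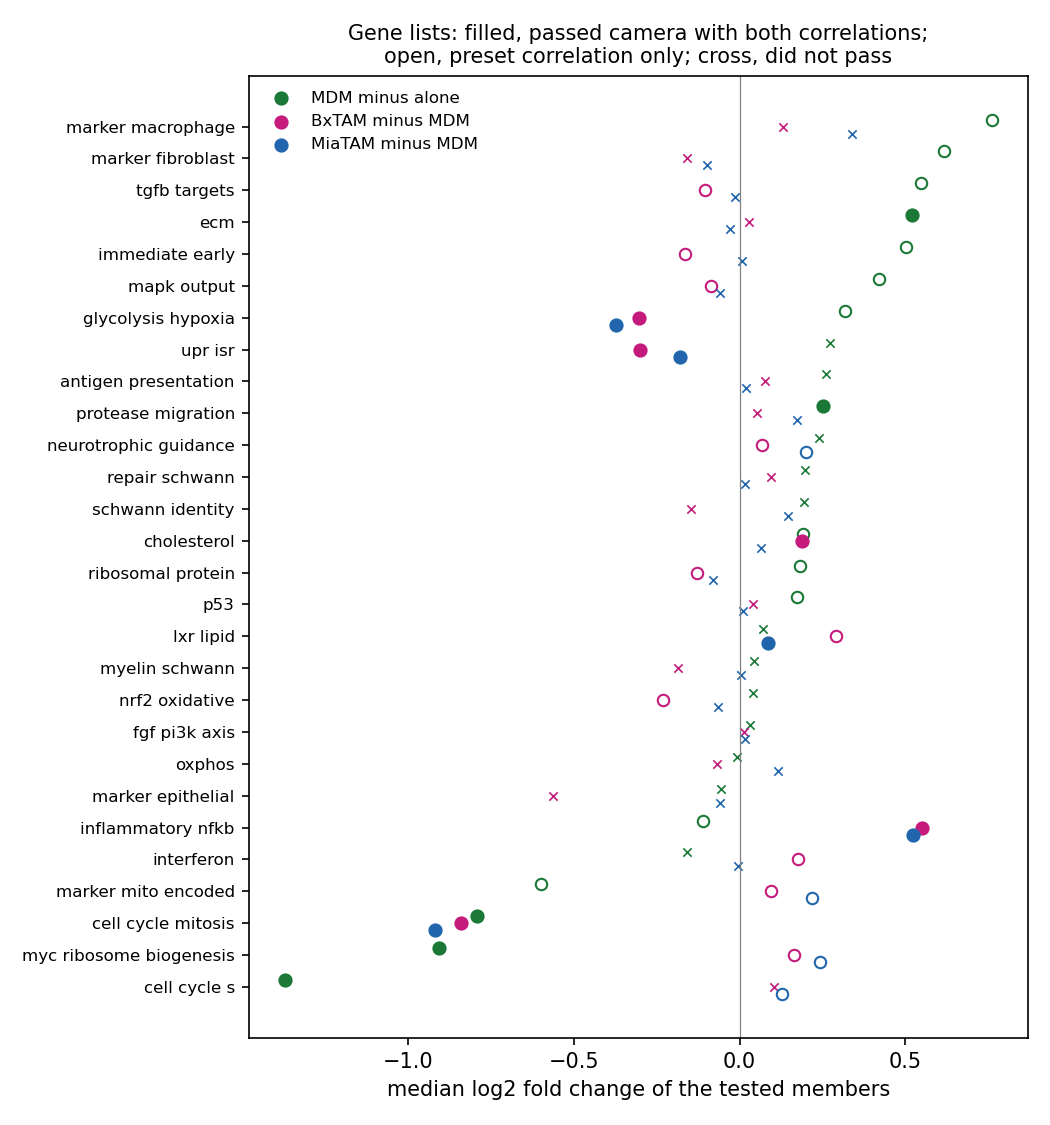
Median log2 fold change of the tested members of 28 gene lists in MDM co-culture against cells alone and in each TAM co-culture against MDM. Filled points passed camera with the preset and the estimated correlation, open points with the preset alone, and crosses with neither. The mitosis list lies at -0.79, -0.84 and -0.92, while the NF-kappaB list lies above 0 in both TAM comparisons.

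Both kinds of TAM changed many of the same genes against MDM co-culture. Il33, Cxcl1, Csf1, Lif and Clca4l rose in both, and Top2a, Kif11, Hspa5, Dhrs3 and Nptxr fell in both. In all, 1405 genes were higher in both and 1357 lower in both, against 427.3 and 451.3 for independent lists, and 74 genes were called in opposite directions. That last count depended on single libraries, with 30 without MDM library 2, 33 without MDM library 3, 41 without MDM library 1, 40 without BxTAM library 2, 41 without BxTAM library 3 and 116 without MiaTAM library 1. Both comparisons share the 3 MDM libraries. Across genes, which are not independent replicates, Pearson's r was 0.748 and Spearman's rho 0.676, against 0.487 and 0.449 for simulated unchanged groups. Pearson's r was lower with no filter on low counts (0.536) and with the DESeq2 test (0.560), settings for which no groups were simulated. In those settings 2674 and 2367 genes were called in the same direction by both. The covariance was 0.0840 against a simulated 0.0113, a difference of 0.0726. The excess over the simulated values says how alike both changes were and not what caused them.

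**Figure D4:**
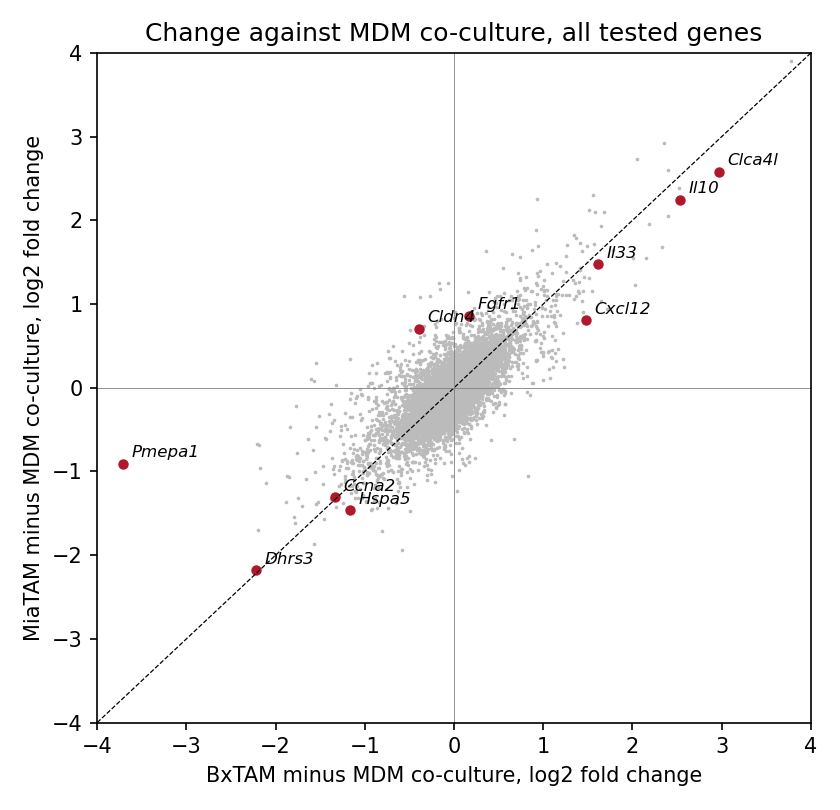
Log2 fold change against MDM co-culture of each of 12360 tested genes, for BxTAM on the horizontal and MiaTAM on the vertical axis, with equal changes on the dashed line and 10 genes named. Il33, Il10 and Clca4l rose in both, Pmepa1 fell further with BxTAM, and Cldn4 fell with BxTAM and rose with MiaTAM.

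The direct comparison of MiaTAM with BxTAM co-culture asked whether both kinds of TAM act alike. Sterol genes were lower with MiaTAM. Hmgcs1, which makes HMG-CoA for the mevalonate pathway, changed by -0.59 ± 0.04, Idi1, an isomerase of that pathway, went from 102 ± 4.63 to 60.1 ± 7.53 CPM, and Insig1, a sterol sensor partner, changed by -0.53 ± 0.04. In the cholesterol list, 1 of 26 tested members rose and 15 fell (1 and 16 adjusted over the list alone), with a median of -0.20 (camera, adjusted p = 1.7e-13), the 1 list that held with an estimated correlation. Higher with MiaTAM were Cldn4, a tight junction protein (1.10 ± 0.08), and Pmepa1 (2.81 ± 0.31). Cxcl12 was lower with MiaTAM (-0.68 ± 0.04).

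Smaller differences ran through other groups. In the oxidative phosphorylation list, 18 of 33 tested members rose and 0 fell (18 and 0 adjusted over the list alone) (camera, adjusted p = 1.0e-05; adjusted p = 0.152 with an estimated correlation), with Ndufb10, a complex I subunit, at 0.32 ± 0.05. In the interferon list, 1 of 38 tested members rose and 13 fell (1 and 18 adjusted over the list alone) (camera, adjusted p = 1.7e-04; adjusted p = 0.0861 with an estimated correlation), with Eif2ak2, the double-stranded RNA kinase, at -0.43 ± 0.05. In the NRF2 list, 11 of 21 tested members rose and 0 fell (11 and 1 adjusted over the list alone) (camera, adjusted p = 0.00149; adjusted p = 0.0511 with an estimated correlation), with Nqo1, a quinone reductase, at 0.29 ± 0.06. The immediate early list had a median of 0.18 (camera, adjusted p = 0.00603; adjusted p = 0.130 with an estimated correlation) and the epithelial marker list, with Cldn4 its 1 called member, one of 0.43 (camera, adjusted p = 0.00596; adjusted p = 0.0861 with an estimated correlation). Fgfr1 was higher with MiaTAM (0.70 ± 0.15) and so were Dhh (0.35 ± 0.07) and Erbb3 (0.48 ± 0.11). The Schwann identity list did not pass (camera, adjusted p = 0.0516), but did without BxTAM library 3, MDM library 2 or MDM library 3 (adjusted p = 0.0485, 0.0476 and 0.0413). Mitosis genes were split, with Plk1, a mitotic kinase, at 0.33 ± 0.06 and Cenpe, a kinetochore motor, at -0.57 ± 0.07, and the list did not pass (camera, adjusted p = 0.769). The signs of median, mean and test differed in the glycolysis, NF-kappaB, neurotrophic and repair Schwann lists, none of which passed.

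Other list calls between both TAM co-cultures lay close to the threshold and were lost without some of the libraries or with another filter on low counts, whether or not the median moved. The mitochondrially encoded list (median 0.12; camera, adjusted p = 0.0246; adjusted p = 0.540 with an estimated correlation) missed the threshold without MiaTAM library 3 (median 0.06, adjusted p = 0.211). The unfolded protein list (median -0.08; camera, adjusted p = 0.0386; adjusted p = 0.139 with an estimated correlation) missed it without BxTAM library 1 (median -0.06, adjusted p = 0.0714) or MiaTAM library 3 (median -0.10, adjusted p = 0.0602), and with a mean of at least 5 CPM (adjusted p = 0.0875). The protease list (median 0.0189; camera, adjusted p = 0.0447; adjusted p = 0.130 with an estimated correlation) missed it without BxTAM library 1, MiaTAM library 1 or MiaTAM library 3 (adjusted p = 0.0714, 0.0988 and 0.0543; medians 0.00583, 0.0201 and 0.0344), with a mean of at least 5 CPM (adjusted p = 0.0875) and with no filter (adjusted p = 0.143). The TGF-beta list (median 0.0464; camera, adjusted p = 0.0358; adjusted p = 0.157 with an estimated correlation) missed it without BxTAM library 1 or 3 and without MiaTAM library 2 or 3 (adjusted p = 0.0521, 0.0513, 0.0529 and 0.0551; medians 0.0413, 0.0139, 0.0230 and 0.0246), without Pmepa1 (adjusted p = 0.0991), with a mean of at least 5 CPM (median 0.00517, adjusted p = 0.213) and with no filter (adjusted p = 0.105). The macrophage marker list (median 0.15; camera, adjusted p = 0.0447; adjusted p = 0.141 with an estimated correlation) missed it without BxTAM library 1 or 2, MiaTAM library 1 or 3, or library 3 of cells alone (adjusted p = 0.0714, 0.0577, 0.0648, 0.0865 and 0.0507), with medians from 0.15 without MiaTAM library 3 to 0.25 without BxTAM library 1, and with no filter (adjusted p = 0.143), with upper-quartile factors, chosen after seeing the data (adjusted p = 0.0577), and with the replicate number as a block (adjusted p = 0.0537). Il33 was lower with MiaTAM by a small margin (-0.14 ± 0.04, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0286), and the call was lost without BxTAM library 1, BxTAM library 2 or MiaTAM library 2 (log2 change -0.14, -0.10 and -0.10). Myc, Gfap and Fgf2 were not called (0.05 ± 0.06, -0.08 ± 0.25 and -0.03 ± 0.15). Ngfr was not called either (0.81 ± 0.37), but passed without MiaTAM library 2 (1.08).

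By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2997 of 12360 genes differed between both TAM co-cultures, 1356 higher and 1641 lower with MiaTAM, and 28 were higher and 5 lower by 2-fold or more. With upper-quartile factors, chosen after seeing the data, the larger direction turned, with 1621 higher and 1406 lower. The count dropped to 1978 without BxTAM library 2, 1976 without BxTAM library 3 and 1933 without MiaTAM library 2.

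Against Schwann cells alone, both TAM co-cultures kept the fall of proliferation genes. With BxTAM, Top2a went from 617 ± 7.77 to 159 ± 4.65 CPM and Mcm3 changed by -1.84 ± 0.05; with MiaTAM the changes were -2.01 ± 0.04 and -1.72 ± 0.05. Tk1, a thymidine kinase, fell 5.13-fold with BxTAM. Il33 stood above its level alone in both, by 0.63 ± 0.05 with BxTAM and 0.50 ± 0.05 with MiaTAM. Gfap was lower in both (-1.09 ± 0.21 and -1.17 ± 0.22) and Fgfr1 higher (1.10 ± 0.19 and 1.79 ± 0.17). Fgf2 was called in neither (0.27 ± 0.15 and 0.24 ± 0.15), but passed with MiaTAM without MiaTAM library 2 (0.36).

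The mitosis lists had medians of -1.77 with BxTAM and -1.75 with MiaTAM (camera, adjusted p = 3.9e-105 and 1.0e-93), with 29 of 29 tested members lower in each and as many adjusted over the list alone. The S-phase medians were -1.26 and -1.19 (camera, adjusted p = 5.2e-51 and 4.1e-41). Matrix genes rose in both (medians 0.63 and 0.52; camera, adjusted p = 4.3e-12 and 2.1e-09), with Col18a1, a basement membrane collagen, at 1.10 ± 0.04 and 1.43 ± 0.04. The protease list rose too (camera, adjusted p = 1.3e-07 and 8.5e-09). In the cholesterol list with BxTAM, 23 of 26 tested members rose and 0 fell (23 and 0 adjusted over the list alone) (camera, adjusted p = 5.0e-10), and with MiaTAM, 14 of 26 tested members rose and 2 fell (13 and 2 adjusted over the list alone) (camera, adjusted p = 0.00338; adjusted p = 0.0806 with an estimated correlation). These lists, except cholesterol with MiaTAM, held with an estimated correlation. In all, 13 lists passed camera with BxTAM and 14 with MiaTAM, and 6 and 7 held with an estimated correlation. The fibroblast marker list was higher and passed in both, but missed the threshold with no filter on low counts (camera, adjusted p = 0.112 and 0.0647). With BxTAM it was also lost without BxTAM library 2, MiaTAM library 1 or library 3 of cells alone (camera, adjusted p = 0.0579, 0.0507 and 0.0622). The same held with upper-quartile factors, chosen after seeing the data (camera, adjusted p = 0.0522). The mitochondrially encoded list was lower and passed with BxTAM, but missed the threshold with a mean of at least 5 CPM (camera, adjusted p = 0.0689). It also missed it without library 3 of cells alone (camera, adjusted p = 0.0512). In the macrophage marker list with BxTAM, 6 of 7 tested members rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 1.13 (camera, adjusted p = 0.0172; adjusted p = 0.0817 with an estimated correlation). With MiaTAM, 6 of 7 tested members rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 1.27 (camera, adjusted p = 0.00247; adjusted p = 0.0341 with an estimated correlation). Pmepa1 with MiaTAM had 128 counts and Sulf2 65 against 0 alone, at least 44.1-fold and 22.4-fold higher by the floor of 3 counts, or 35.3-fold and 17.7-fold by the lower 95% counting limit, and Tspan18 had 103 against 1, with a 95% counting interval of the ratio from 18.7 to 4242.

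By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7524 genes differed from cells alone with BxTAM, 3710 higher and 3814 lower, and 8041 with MiaTAM, 3877 higher and 4164 lower. With upper-quartile factors, chosen after seeing the data, the larger direction turned, with 4348 higher and 3213 lower for BxTAM and 4664 and 3446 for MiaTAM. Of the main calls, 3075 were higher in both and 3261 lower in both, against 1164 and 1285 for independent lists, and r across genes was 0.926 against 0.502 for simulated unchanged groups with the same controls. The covariance was 0.339 against a simulated 0.0121, a difference of 0.327. Myc was lower with BxTAM (-0.17 ± 0.06), a call lost without BxTAM library 2 or 3 or library 2 or 3 of cells alone (log2 change -0.13, -0.17, -0.16 and -0.14). With MiaTAM it was not called (-0.12 ± 0.06), but passed without MiaTAM library 2 (-0.20). Ngfr was higher with MiaTAM (1.73 ± 0.42) and not called with BxTAM (0.91 ± 0.47). With BxTAM it passed without library 3 of cells alone (1.45) and in a fit of only the 2 groups compared (0.91).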

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

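Results in this part stood out by a difference between both TAM co-cultures, taken from the direct test of MiaTAM against BxTAM, or by their size. All tests of explanations here were chosen after the result was seen, except the 2 that used separate MDM libraries on each side, which were written before.

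The first pattern is the fall of proliferation genes, in S phase and mitosis with MDM and further in mitosis with both TAM. RNA of non-dividing cells mixed into the Schwann cell RNA would lower both lists alike. The median of the mitosis list minus that of the S-phase list was 0.58 with MDM against alone (95% bootstrap interval 0.23 to 0.91). It was -0.95 with BxTAM against MDM (-1.14 to -0.73) and -1.05 with MiaTAM against MDM (-1.24 to -0.84). The intervals come from 2000 draws over genes within each list and do not measure the spread between libraries. Members of a list are correlated (estimated at 0.19 for mitosis with MDM against alone), so the intervals may be too narrow. Within that limit, the differences argue against dilution as the whole cause. A denser culture at harvest may lower Ctgf and Cyr61, whose mean change was 0.27 with MDM, -1.09 with BxTAM and -1.17 with MiaTAM, so density cannot be told apart from a response to TAM by these 2 genes. With MDM against alone the mean change was above 0 (0.22 to 0.33 with its standard error), the other way from a denser culture. These 2 genes do not decide without a label of density. A slower cell cycle and culture density both stay open.

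The second pattern concerns genes called both for MDM against alone and for a TAM against MDM. More of them moved back from the MDM level, in the direction of cells alone, than further away. With BxTAM, 1262 genes were higher with MDM and lower with BxTAM, and 1316 the reverse, against 683.6 and 713.3 for independent lists. With MiaTAM the numbers were 1232 and 1347, against 834.2 and 812.7. Both comparisons hold the MDM level, with opposite sign, so numbers above those for independent lists can arise without a move towards cells alone. Further from cells alone moved 311 genes higher and 444 lower with BxTAM, against 688.4 and 708.3, and 466 and 693 with MiaTAM, against 784.3 and 864.4. Compared directly with cells alone, 8047 genes differed with MDM, 7524 with BxTAM and 8041 with MiaTAM. At 2-fold or more the numbers were 1046, 934 and 1104. By these counts MiaTAM co-culture as a whole was no nearer to cells alone than MDM co-culture was. The correlation across genes, however, was -0.386 for BxTAM and -0.239 for MiaTAM, nearer 0 than the -0.490 and -0.484 of simulated unchanged groups, and such a pattern arises by chance from the 3 shared MDM libraries, so the covariance was taken again with separate MDM libraries on each side. It was -0.0597 for BxTAM (-0.0615 to -0.0582 over 3 splits) and -0.0341 for MiaTAM (-0.0357 to -0.0332). These values lay below the lowest simulated values of -0.0130 and -0.0132 for shared libraries. That argues against chance values of the shared libraries as the whole cause, but it is no test of a move towards cells alone. The MDM level still enters both changes with opposite sign, so any change particular to MDM co-culture also makes the covariance negative. A shift of the whole MDM group in handling or batch may give the same values, since both TAM changes correlate at r = 0.748, and cannot be told apart from an effect of induction.

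The third pattern is Pmepa1, Sulf2 and Tspan18 near 0 counts in cells alone. Rat macrophage RNA would bring abundant macrophage transcripts with it, but the median macrophage marker stood at 0.0841 CPM in MDM co-culture against 4.44 CPM for Pmepa1, which argues against it as the source of Pmepa1, although 6 of 7 tested markers rose, while RNA of macrophages of another species stays open. TGF-beta signalling is a possible cause, and its target list without Pmepa1 had an adjusted p of 0.0229 (camera), but 0.108 for the whole list with an estimated correlation, so it cannot be told apart. A different stock or batch of cells alone may also set them apart, as the component with 56.5% of the variance did, and cannot be told apart from a response to co-culture. Pmepa1 also differed among the co-cultures, by -3.71 with BxTAM and -0.90 with MiaTAM against MDM. A different stock of cells alone does not bear on that difference. All 3 genes lie on chromosome 3.

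The other splits of the 6 libraries in each comparison number 10 with the real one, so the share of splits with as many genes is never under 0.05, and only 1 split of each, the real one, reached its number. The real split gave 8039 genes for MDM against alone and the highest other 0, 4642 and 2 for BxTAM against MDM, 4696 and 2 for MiaTAM against MDM, 7607 and 0 for BxTAM against alone, 7732 and 0 for MiaTAM against alone, and 2731 and 2 for MiaTAM against BxTAM.

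Of the genes named for either TAM against MDM, these were higher with MiaTAM than with BxTAM: Pmepa1 (2.81 ± 0.31), Fgfr1 (0.70 ± 0.15), Ccne1 (0.37 ± 0.09), Angptl4 (0.32 ± 0.04), Nptxr (0.25 ± 0.05), Lif (0.24 ± 0.08), Kif20a (0.23 ± 0.04) and Egr1 (0.16 ± 0.04). Lower with MiaTAM were Il33 (-0.14 ± 0.04), Cxcl1 (-0.15 ± 0.05), Car12 (-0.19 ± 0.06), Hsp90b1 (-0.22 ± 0.04), Msmo1 (-0.23 ± 0.04), Cxcl10 (-0.25 ± 0.06), Csf3 (-0.26 ± 0.06), Mmp13 (-0.28 ± 0.07), Hspa5 (-0.29 ± 0.05), Parp14 (-0.35 ± 0.05), Clca4l (-0.38 ± 0.07), Ddit3 (-0.53 ± 0.07) and Cxcl12 (-0.68 ± 0.04). Calls of Il33 and Lif were lost without some of the libraries: without BxTAM library 2 the adjusted p (edgeR quasi-likelihood, Benjamini-Hochberg) was 0.167 and 0.173, and without MiaTAM library 2 it was 0.136 and 0.168. Without BxTAM library 1 it was 0.0562 for Il33, and without BxTAM library 3 0.145 for Lif. Libraries were left out only for genes that the naming rule picks for MiaTAM against BxTAM, so other genes listed here may be unchecked. By the same test Cxcl1 lay closest to the threshold among the listed genes (adjusted p = 0.0444).

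Lists that differed by camera were cholesterol, with a median of -0.20, oxidative phosphorylation (0.14), interferon (-0.19), NRF2 (0.18), epithelial markers (0.43), immediate early genes (0.18), mitochondrially encoded genes (0.12), TGF-beta targets (0.0464), the unfolded protein response (-0.0844), macrophage markers (0.15) and proteases (0.0189). Of these 11 lists, only cholesterol passed with an estimated correlation (1 list).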

How the results depend on the processing

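Most calls of named genes kept their direction and their side of the threshold. Most of these genes were named for a large change or a small p, so they are a selected set. Over all genes, 1861 of the 2997 calls for MiaTAM against BxTAM were kept without MiaTAM library 2. Without BxTAM library 3 it was 1907, and with the DESeq2 test 2490. For MDM against alone, 7247 of 8047 calls were kept with the DESeq2 test. The balance of higher and lower genes was not stable, and its larger direction turned with upper-quartile factors in all 6 comparisons. Of 743 changes of named genes, 741 kept their call with library totals only and 740 with upper-quartile factors, both chosen after seeing the data, 742 with the size factors of DESeq2, and 743 with limma-voom. With the DESeq2 test 715 kept their call and 9 lost it, and the remaining changes had no DESeq2 value. List calls depended on the filter and on the assumed correlation. Of 168 list results, no filter on low counts gained 10 calls and lost 10, and a mean of at least 5 CPM, which left some lists too short to test, gained 1 and lost 8. With an estimated correlation, 5 lists passed for MDM against alone, 5 for BxTAM against MDM, 5 for MiaTAM against MDM, 6 for BxTAM against alone, 7 for MiaTAM against alone and 1 for MiaTAM against BxTAM. With fry the numbers were 24 for MDM against alone, 23 for BxTAM against MDM, 20 for MiaTAM against MDM, 26 for BxTAM against alone, 26 for MiaTAM against alone and 17 for MiaTAM against BxTAM. An estimated correlation replaces the preset by construction, while fry changes both the treatment of correlation and the question asked, a list against no change in place of a list against other genes, and which of these moved the counts was not tested. With a mean of at least 5 CPM, 6 lists passed for MiaTAM against BxTAM, with fewer genes tested. Leaving out each library gave 1933 to 3113 genes and 6 to 12 lists for MiaTAM against BxTAM, with fewer libraries, and 2245 to 2864 genes shared in direction by both TAM and 30 to 116 called in opposite directions. Changes that were not called turned sign without single libraries, and the cause was not tested: Gfap ran from -0.0336 to 0.310 for BxTAM against MDM, from -0.165 to 0.165 for MiaTAM against MDM and from -0.284 to 0.0723 for MiaTAM against BxTAM, Fgf2 from -0.0276 to 0.1001 for MDM against alone and from -0.121 to 0.0906 for MiaTAM against BxTAM, and Myc from -0.0232 to 0.0974 for MiaTAM against BxTAM. Il33 between both TAM missed the threshold with upper-quartile factors (adjusted p = 0.0528). Libraries that share only a number were not paired: of 18 same-number pairs, 0 correlated above 0.1 (-0.127 to 0.0892), and 2 of 12 libraries matched their own number best. With the replicate number as a block, 8046 genes changed for MDM against alone, 4275 for BxTAM against MDM, 5059 for MiaTAM against MDM, 7496 for BxTAM against alone, 8021 for MiaTAM against alone and 2993 for MiaTAM against BxTAM, of which 7966, 4181, 4949, 7426, 7956 and 2887 were also called without the block. Among named genes and lists, Acta2 for BxTAM against MDM, Cryab and Mtcp1 and the macrophage markers for MiaTAM against BxTAM lost their calls, while the protease list for MiaTAM against MDM gained one, and the block changed no other call of a named gene or list. Without the cell cycle lists, chosen after seeing the data, 2719 genes were shared in direction by both TAM. Of all changes of named genes, leaving out 1 library lost 112 calls over all libraries and gained 5, and of list calls it lost 25 and gained 17. At this depth, genes with few counts, such as Ngfr and Gfap, have wide errors.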

Other observations

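The neuronal pentraxin receptor gene Nptxr, better known from synapses, was among the stronger changes. It stood at 91.6 CPM in cells alone, a value chosen after it was seen, 588 ± 10.5 with MDM, 170.3 ± 7.51 with BxTAM and 203 ± 12.3 with MiaTAM. Of 13 tested genes of the mitochondrial chromosome, 11 fell with MDM and 2 rose, and the same numbers passed adjusted over the list alone. Among the falls, Mt-atp6 differed widely between the libraries of cells alone. Scaled by library total only, it stood at 2134 ± 2033 CPM alone and 696 ± 22.7 CPM with MDM. The share of all counts from that chromosome was not lower, at 5.52, 5.92 and 5.77% with MDM and 5.54, 5.03 and 5.42% in cells alone. Mt-nd4, a complex I subunit, changed by -1.03 ± 0.05. The genes that rose, named after their values were seen, were Mt-co1 (0.48 ± 0.05), the gene with the most counts in every library, and Mt-cox3 (0.27 ± 0.05).

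Of the 74 genes called in opposite directions by both TAM against MDM, 53 were higher with BxTAM and lower with MiaTAM and 21 the reverse. The 74 ranged from 30 without MDM library 2 to 116 without MiaTAM library 1. Cxcl12 stood at 234 ± 1.35 CPM alone, 79.1 ± 3.63 with MDM, 221 ± 4.65 with BxTAM and 138 ± 2.85 with MiaTAM.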
